A study of Mus musculus with 6 samples.

How the data were processed

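RNA was measured in 6 libraries of CD8+ T cells from gBT-I mice, which carry a transgenic T cell receptor for a peptide of herpes simplex virus glycoprotein B. Per the labels, spleen cells were activated in culture with that peptide and lipopolysaccharide, given IL-2 from day 2 to day 5, and harvested on day 6. The treated cultures received butyrate, a short-chain fatty acid and histone deacetylase inhibitor, from day 3. There were 3 control and 3 butyrate libraries. Per the labels, RNA was extracted with Trizol and 1 µg of total RNA entered an Illumina TruSeq RNA library kit. Sequencing on a Genome Analyzer IIx is given in the series design. The sources used here do not say how many cells were other than CD8+ T cells, nor whether the cells were sorted.

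The authors deposited 1 table of raw read counts per gene, with 1 column per library and genes given by number. The submitters' processing notes name CASAVA, TopHat, Picard, featureCounts, Subread and edgeR and the genome build mm10, with no versions. The roles and parameters of these tools, the strand setting and the treatment of reads shared between near-identical genes are not given in the sources used here. Counts of paralogs (the Ifi200 family, Ly6c1, granzymes, histone genes, class II genes, Bcl2a1d and Hbb-b1) and of overlapping or antisense genes are therefore uncertain. Each column was matched to its sample by the label that names it.

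The table holds 27179 gene numbers. Of these, 25275 were named from a RefSeq gene table of GRCm38.p6, the assembly that mm10 is made from, and 18 from GENCODE. The 1886 numbers with no name held 0.961% to 1.20% of the counts of a library and were kept in the tests. Coordinates are those of the RefSeq table, 1-based.

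Library totals ran from 5383380 to 6244350 counts. A gene with 3 counts in a library, the limit that a count of 0 allows, stood at 0.480 to 0.557 CPM (counts scaled to a common library total). Reads carry no molecular identifiers in the sources used here, so intervals and limits of this kind cover counting error only. The libraries of a group differed by more than sampling noise (chi-square per degree of freedom of 5.43 to 10.6 over genes with at least 20 counts), so each was counted as a replicate. The labels do not say that replicates came from separate mice or cultures, so the p-values measure the spread between these samples, which may be technical.

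Butyrate was compared with control by edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with TMM normalization, the filterByExpr filter and Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 are called higher or lower. The filter left 11740 genes. Standard errors are the size of the log2 fold change divided by the square root of F. Values per group are means ± SD of TMM-scaled CPM (n = 3), and a gene said to rise or fall by a value did so on the log2 scale.

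Gene lists, 37 in all with 1210 entries, were fixed before the data were examined, and 1199 entries were matched to a gene number. They cover T cell effector, memory, inhibitory, homing and cytokine genes, markers of other spleen cells, chromatin genes, metabolism, cell cycle, death, interferon and ribosomal genes. A list with at least 5 tested members was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with adjustment over the 36 lists tested. Beside each count of called members stands the count adjusted over the list alone. Lists share some members.

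Genes are named in the text by a rule fixed before the data were examined. The first part takes the 8 genes with the largest rises and the 8 with the largest falls among called genes with a mean of at least 10 CPM and no overlap between the groups, predicted genes left out. The second part is a panel of 18 genes, taken whatever they showed. The third part takes, per described list, up to 2 called members per direction with the smallest p, or the most abundant member where none was called. Some genes that the rule takes are not reported here. Genes named outside the rule are said to be chosen after their values were seen. Tested genes were also split into tertiles by mean log2 CPM over all 6 libraries, with boundaries at 21.1 and 66.4 CPM, and the percent of calls of at least 2-fold that were higher was taken in each.

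Alternatives fixed before the data were examined were RLE, upper quartile and total-count scaling, TMM without the 50 most abundant genes, no filter, a filter of at least 5 CPM in 3 libraries, DESeq2 (1.42.0), limma voom, robust edgeR, the replicate number as a block, each library left out in turn, glmTreat against a fold of 1.5, camera with an estimated correlation or a prior count of 0.5, fry, and tertiles with no fold minimum. A replicate block with transcript length and GC offsets was added after the data were seen.

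Control and butyrate libraries share replicate numbers, which the labels do not tie to a mouse, culture or day. After subtraction of the group means, libraries with the same number correlated across genes at 0.362, 0.197 and 0.353. Every pair with different numbers correlated below 0, at -0.301 to -0.0746. Subtracting the mean of 3 libraries makes these values negative on average where same-number values are positive, so they are not separate evidence of pairing. By the rule set for this, the numbers were taken to pair the libraries. The main test has no block, and the blocked value is printed where it changes a call.

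The tests were run on simulated data made for this comparison, with counts drawn for 11601 tested genes. edgeR's test recovered 39.4% of the 66 genes changed 1.5-fold, 80.3% of the 66 changed 2-fold and 96.9% of the 65 changed 4-fold, and called 15 of 11404 unchanged genes. These made up 9.55% of its calls, more than the threshold of 0.05 on the adjusted p allows on average. In the simulated lists, camera called the 1 shifted list and 0 of the 34 lists that shared no gene with it. These counts do not measure camera's false calls where the genes of a list move together. In the measured data, the correlation estimated within a list ran from -0.075 (CD4 helper and regulatory T cell genes) to 0.518 (mitochondrially encoded genes). For cholesterol synthesis, a list called down, it was 0.433. Figures were drawn with matplotlib.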

Results

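The 6 libraries comprised 3 of activated gBT-I CD8+ T cells cultured without butyrate and 3 cultured with it from day 3 to the harvest on day 6. Control libraries held 5566196, 5415021 and 6244350 counts, and butyrate libraries 5401428, 5809517 and 5383380. The comparison asks how butyrate, a product of gut bacteria that inhibits histone deacetylases, alters the transcriptome of activated CD8+ T cells. Genes with at least 1 count numbered 14220 ± 139 in a control library and 15157 ± 91.7 in a butyrate library (SD, n = 3). The exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries can give. The 20 most abundant genes took 6.08% ± 0.0362 of the counts in control and 7.17% ± 0.098 with butyrate (SD, n = 3, exact permutation p = 0.1).

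Butyrate was followed by a change in 45.9% of the genes tested. Prf1, Lta, Il10 and Il2ra were among the genes that rose, and 47 of 55 mitosis genes and 19 of 24 cholesterol synthesis genes fell. Of 11740 genes tested, 2756 were higher and 2637 lower by edgeR's adjusted p, and 1249 were higher and 391 lower by at least 2-fold. The first principal component held 80.1% of the variance and parted the groups. The groups did not overlap for 57.1% of genes, against 10% by chance. Higher genes made up 51.1% of the calls, and 61.8% with upper quartile scaling. camera called 8 of 36 gene lists up and 4 down. With an estimated correlation it called 0, with 0 lists at an unadjusted p under 0.05, while fry, which asks only whether a list's own genes move one way, called 21. Under the other 9 splits of the 6 libraries, each with both groups on both sides, camera with the preset correlation called 6 to 17 lists. Under every alternative other than the estimated correlation, 11 of the 12 lists were called again, at an adjusted p of at most 0.0473.

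**Figure D1:**
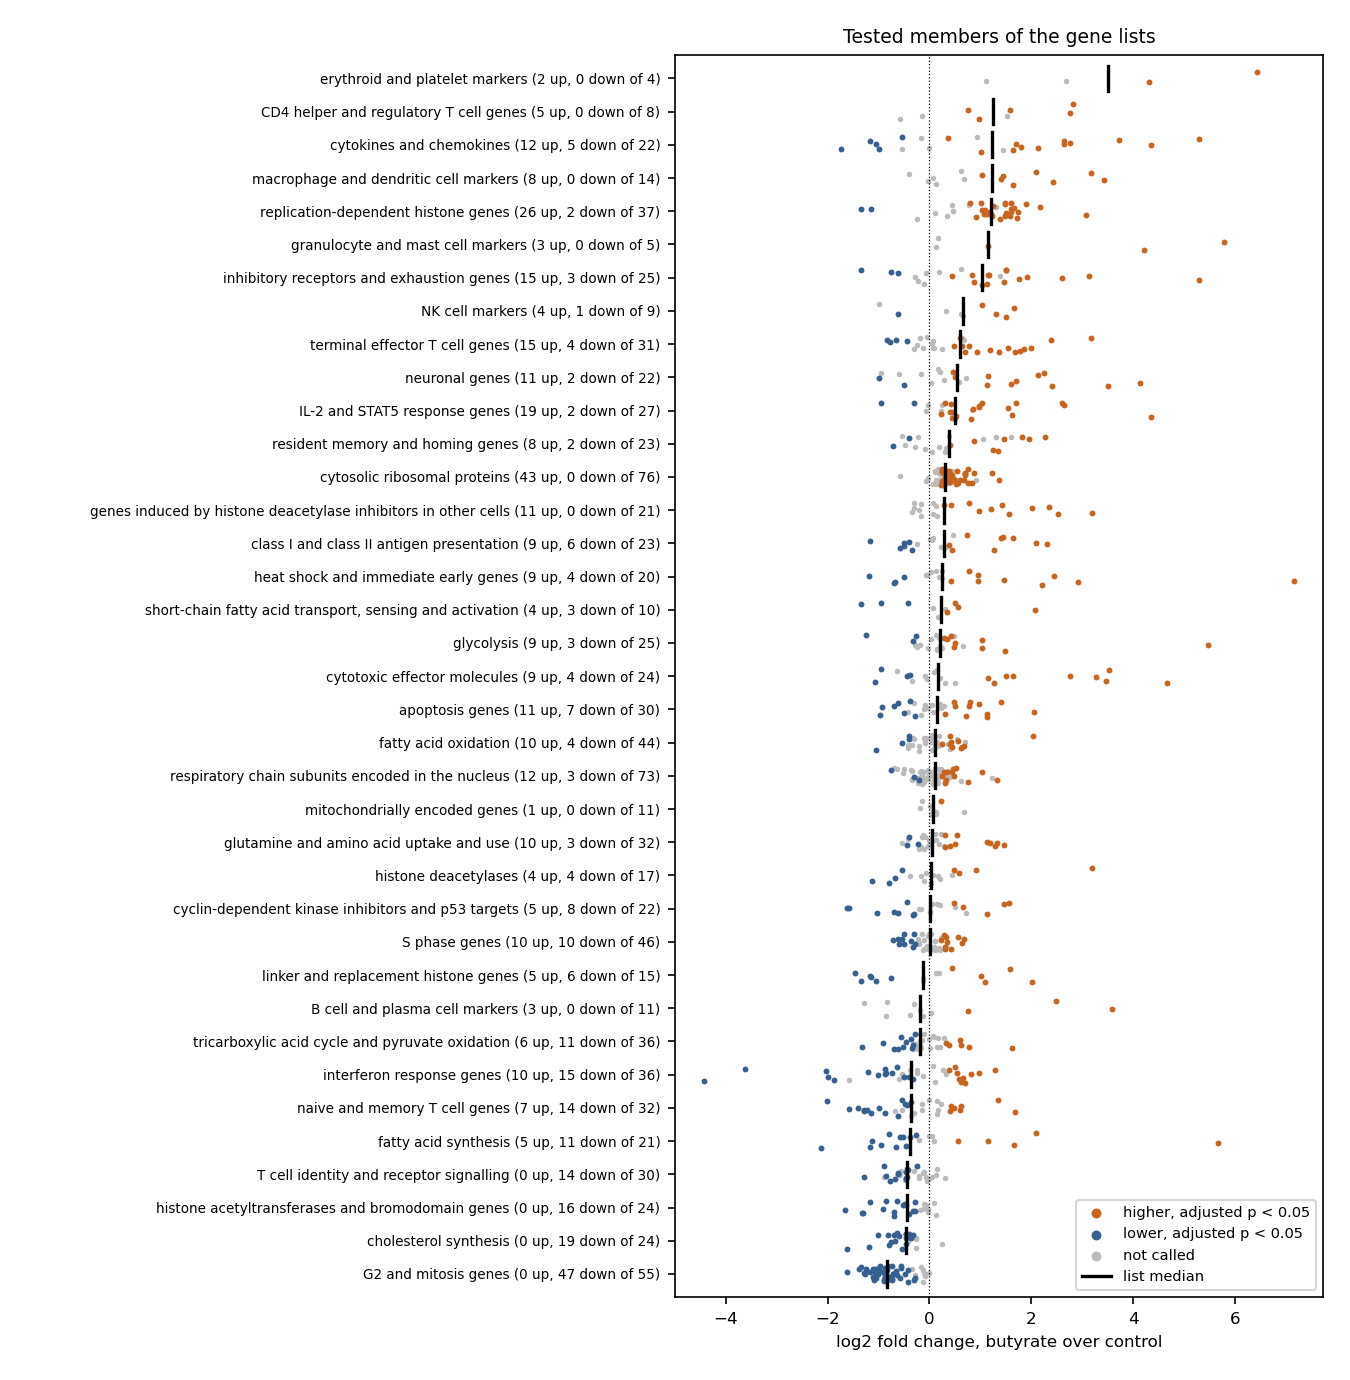
Log2 fold change (butyrate over control, x axis) of every tested member of each gene list (rows, with the number called higher and lower), coloured by call, with the list median as a bar. The mitosis list has 47 of 55 members lower and none higher, and the ribosomal protein list 43 of 76 higher and none lower. 1 point of the heat shock list at the far right, Hspb1, has no counts in control, so its fitted value is not a measured fold.

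Among the largest rises was Miat, a long noncoding RNA on chromosome 5 (112213228 to 112228948, gene 330166), at 2.22 ± 0.22 CPM in control and 141 ± 22.2 CPM with butyrate (SD, n = 3). Its log2 fold change was 5.98 (SE 0.183, adjusted p = 1.82e-06). Il10, which encodes an anti-inflammatory cytokine (chromosome 1, 131019845 to 131024970, gene 16153), went from 0.830 ± 0.998 to 33.0 ± 10.5 CPM. Plet1, the guanine nucleotide exchange factor gene Rasgrf1, Zcchc14, the muscarinic receptor gene Chrm4, the p53 family gene Trp73 and the phosphatase subunit gene Ppp2r2c rose by log2 fold changes of 4.78 to 6.07. The size of several of these folds hung on a few control counts. Without control replicate 3 the log2 fold change was 6.69 for Plet1 (6.07 with all libraries), 6.18 for Zcchc14 (5.53), 5.92 for Ppp2r2c (4.78) and 5.50 for Trp73 (4.90). It was 6.88 for Il10 without control replicate 1 (5.29 with all libraries), and 6.74 for Rasgrf1 without control replicate 2 (6.03).

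Of the genes that fell most, Ly6c1, which encodes a surface protein of the Ly6 family (chromosome 15, 75044018 to 75048920, gene 17067), went from 33.8 ± 21.7 to 1.38 ± 0.574 CPM (log2 fold change -4.58, SE 0.734, edgeR adjusted p = 0.00118). Gpr183, a receptor for oxysterols that guides lymphocyte migration, went from 41.8 ± 8.29 to 4.94 ± 2.44 CPM. Slfn2, a gene linked to T cell quiescence, went from 396 ± 57.2 to 78.4 ± 22.6 CPM. Ifi214, Ifi213 and Ifi203, which lie on chromosome 1 between 173521311 and 173942866, fell by log2 fold changes of 2.69, 2.29 and 2.20. Ifi27l2a fell by 2.32 and Cables1 by 2.18 on the log2 scale. How reads shared within the Ly6c and Ifi200 families were counted is not given in the sources used here, so the split between members is uncertain.

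Genes of the cytolytic granule moved both ways. Prf1, which encodes the pore-forming protein perforin, went from 22.7 ± 11.1 to 580 ± 373 CPM (SD, n = 3), a log2 fold change of 4.66 (SE 0.5, edgeR adjusted p = 0.000175). Gzmc rose from 101 ± 13.4 to 1157 ± 407 CPM, and Gzmb, the most studied granzyme, from 3229 ± 576 to 7120 ± 983 CPM (log2 fold change 1.14, adjusted p = 0.000512). Unc13d, needed for granule priming, and the cathepsin gene Ctsw fell by 1.06 and 0.95 on the log2 scale. Of 24 tested cytotoxic effector genes, 9 rose and 4 fell (10 and 4 adjusted over the list alone), and the list was not called (camera adjusted p = 0.241). Without butyrate replicate 3 the log2 fold change of Prf1 was 4.0.

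The cytokine genes included Lta, which encodes lymphotoxin alpha and went from 52.3 ± 14.5 to 1068 ± 270 CPM, and Lif, which went from 26.1 ± 8.44 to 162 ± 20.8 CPM. Ifng, the gene for interferon gamma, had 5.87 ± 5.21 CPM in control and 40.7 ± 28 CPM with butyrate (log2 fold change 2.76, SE 0.705, edgeR adjusted p = 0.0119). Its groups overlapped, and its log2 fold change was 3.75 without control replicate 3. The call of Ifng was lost with robust edgeR (adjusted p = 0.0563) and limma voom (0.0539), within a range of 7.54e-06 to 0.0563 over its alternatives. Il16 and Ltb, the gene for lymphotoxin beta, fell by 1.04 and 0.54 on the log2 scale. Of 22 tested cytokine and chemokine genes, 12 rose and 5 fell (13 and 5 adjusted over the list alone). The list was not called (camera adjusted p = 0.078) but was called up in 8 of 20 alternatives. These were the replicate block (0.0444), no filter (0.0217), the stricter filter (0.0274), DESeq2 (7.93e-05), fry (0.00666), and the fits without control replicate 3 (0.0202) or butyrate replicate 1 (0.0396) or 2 (0.0273), while the highest value was 0.464.

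Genes that mark naive and memory T cells moved both ways. Of 32 tested, 14 fell and 7 rose (15 and 8 adjusted over the list alone, median log2 fold change -0.37, camera adjusted p = 0.136). In 3 of 20 alternatives the list was called down: without control replicate 3 (camera adjusted p = 0.0428), without butyrate replicate 1 (0.0483) and with no filter (0.0251), and the highest value was 0.723. Cd27, a costimulatory receptor, went from 178 ± 28.3 to 59.6 ± 15.4 CPM (SD, n = 3) and Tnfsf8, the CD30 ligand gene, from 56.1 ± 6.04 to 21.2 ± 3.04 CPM. Myb rose from 35.0 ± 4.72 to 112 ± 17 CPM and Foxo1 by a log2 fold change of 0.63. In the fixed panel, the lymph node homing receptor gene Ccr7 rose from 145 ± 62.4 to 371 ± 99 CPM (log2 fold change 1.36, edgeR adjusted p = 0.00499). Tcf7, which encodes the transcription factor TCF-1, fell by 1.23 (adjusted p = 0.0205) and Il7r, the IL-7 receptor gene, by 0.44 (adjusted p = 0.0284).

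Leaving out single libraries ended the calls of Tcf7 and Il7r. Without control replicate 1 their log2 fold changes shrank to -0.83 (edgeR adjusted p = 0.0644) and -0.25 (0.0719). Without butyrate replicate 2 they were -1.25 (0.0611) and -0.39 (0.094), and without butyrate replicate 3 Il7r was at -0.46 (0.0551), so in these fits the folds stayed near their values while the adjusted p rose. Other settings also ended these edgeR calls: robust fitting for Tcf7 (-1.23, 0.0747), and upper quartile scaling (-0.36, 0.0617) and length and GC offsets with the block (-0.23, 0.0629) for Il7r. Over all alternatives the adjusted p began at 1.87e-05 for Tcf7 and 0.00519 for Il7r.

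Several genes of the terminal effector list rose. Irf4, a transcription factor induced by T cell receptor signals, went from 210 ± 7.34 to 837 ± 69.5 CPM (SD, n = 3), and Batf3 from 17.3 ± 1.9 to 157 ± 51.5 CPM. Il2ra, the high-affinity IL-2 receptor chain CD25, went from 690 ± 37.4 to 2014 ± 311 CPM (log2 fold change 1.54, SE 0.122, edgeR adjusted p = 5.06e-05). Il18rap and Il18r1, the chains of the IL-18 receptor, fell by 0.83 and 0.66 on the log2 scale. Klrg1 was near the detection limit, at 0.790 ± 0.586 and 3.02 ± 0.767 CPM (adjusted p = 0.0113), and its log2 fold change was 2.67 without control replicate 3 and 1.86 with all libraries. Tbx21, which encodes T-bet, did not pass the test (179 ± 3.12 and 173 ± 7.78 CPM, adjusted p = 0.625), while Eomes, the gene of a related factor, fell by 0.61 (adjusted p = 0.00491). Of 31 tested members, 15 rose and 4 fell, the same numbers adjusted over the list alone. camera called the list up (adjusted p = 0.0172), but not with an estimated correlation (adjusted p = 0.446).

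**Figure D2:**
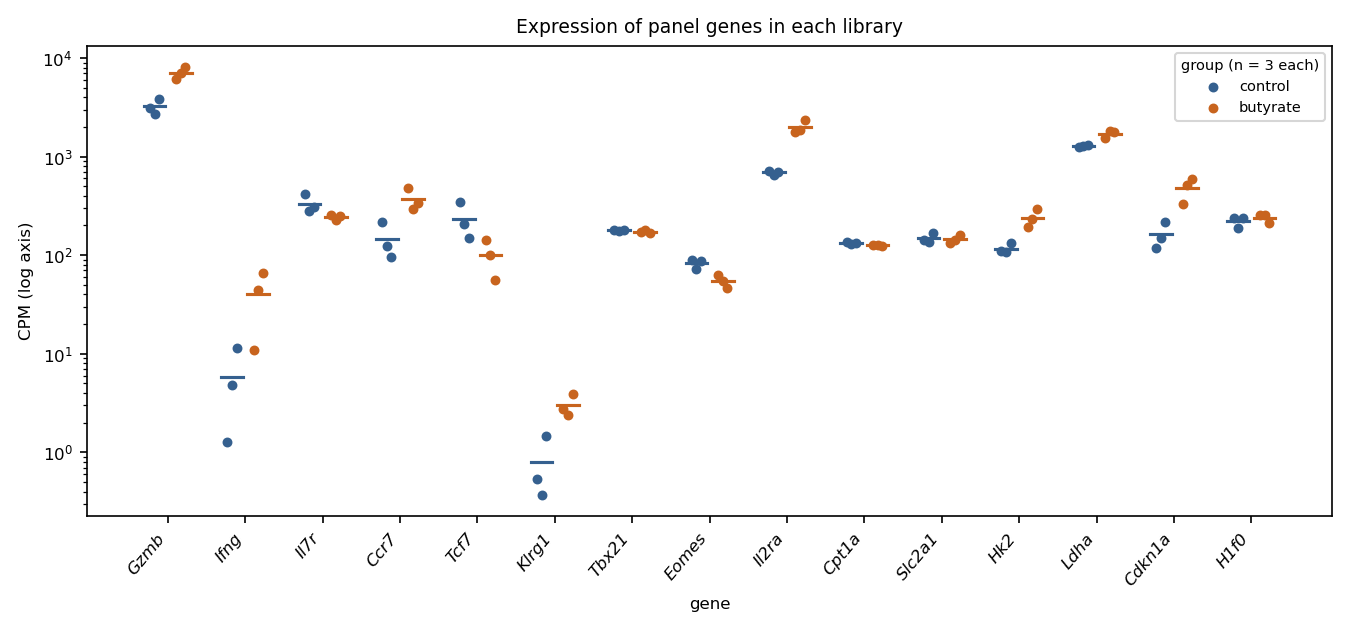
TMM-scaled CPM (log axis) of 15 genes of the fixed panel in each control and butyrate library (points, n = 3 per group), with group means as bars. Il2ra and Gzmb were higher in each butyrate library than in every control library, whereas Ifng overlapped between the groups. Foxp3, also of the panel, was not tested, with 4 counts over the control and 5 over the butyrate libraries.

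Inhibitory receptor and exhaustion genes rose in 15 of 25 tested members and fell in 3 (17 and 3 adjusted over the list alone, median log2 fold change 1.04). Rgs16, a regulator of G protein signalling, went from 11.9 ± 2.17 to 104 ± 14 CPM (SD, n = 3) and Tnfrsf9, which encodes the costimulatory receptor 4-1BB, from 90.6 ± 5.17 to 306 ± 44 CPM. Ikzf2 and Cd160 fell by 0.62 and 0.76 on the log2 scale. camera called it up (adjusted p = 0.00686), but not with an estimated correlation (adjusted p = 0.38). IL-2 and STAT5 response genes rose in 19 of 27 and fell in 2 (22 and 2 adjusted over the list alone, camera adjusted p = 7.39e-05, and adjusted p = 0.38 with an estimated correlation). Besides Lta, they included Myc, a driver of T cell growth, which went from 279 ± 14.6 to 860 ± 97.9 CPM. Pim2, a survival kinase gene, fell by 0.94 on the log2 scale. Resident memory and homing genes rose in 8 of 23 and fell in 2, the same adjusted over the list alone, and were not called (camera adjusted p = 0.182). The chemokine receptor genes Cxcr4 and Ccr4 rose by log2 fold changes of 1.46 and 2.27, and Cxcr6 fell by 0.71.

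T cell identity and receptor signalling genes fell in 14 of 30 and rose in 0, the same adjusted over the list alone (median log2 fold change -0.43). Trbc1, a constant segment of the T cell receptor beta chain, went from 262 ± 44.8 to 107 ± 5.89 CPM (SD, n = 3), and Lcp2, which encodes the adaptor SLP-76, from 251 ± 27.8 to 135 ± 14.9 CPM. The other 16 members were not called. They included Trac (2063 ± 362 and 2552 ± 593 CPM, edgeR adjusted p = 0.191) and Cd8a (454 ± 62.1 and 436 ± 55.1 CPM, 0.741), both chosen after their values were seen. This list was called down (camera adjusted p = 0.000882), but not with an estimated correlation (adjusted p = 0.38). CD4 helper and regulatory T cell genes rose in 5 of 8 tested, from 13 matched, and fell in 0, the same adjusted over the list alone. They were not called (camera adjusted p = 0.0728). They were called up in 6 of 19 alternatives: with no filter (0.0167), DESeq2 (0.0401), limma voom (0.0473) and fry (0.00355), and without control replicate 3 (0.037) or butyrate replicate 3 (0.0449), while the highest value was 0.38. Zbtb7b, the master regulator of the CD4 lineage, went from 69.8 ± 7.06 to 117 ± 6.52 CPM, and Izumo1r from 1.02 ± 0.458 to 6.86 ± 2.75 CPM.

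Markers of other spleen cells moved with treatment as well, and most of those tested stood at low levels. The filter passed 14 of 29 matched macrophage and dendritic cell markers, 9 of 17 NK cell markers and 11 of 23 B cell and plasma cell markers. It passed 5 of 22 granulocyte and mast cell markers and 4 of 16 erythroid and platelet markers. A marker almost silent in control could pass only through the butyrate libraries, and could then only be seen to rise. Macrophage and dendritic cell markers rose in 8 of 14 and fell in 0 (9 and 0 adjusted over the list alone, median log2 fold change 1.22, and 0.58 with no filter). Itgam, which encodes the integrin CD11b, went from 4.08 ± 0.682 to 44.1 ± 9.5 CPM (SD, n = 3), and the class II gene H2-Ab1 from 8.95 ± 0.281 to 38.3 ± 5.67 CPM. This list was called up (camera adjusted p = 0.00509), but not with an estimated correlation (adjusted p = 0.38). NK cell markers rose in 4 of 9 and fell in 1 (5 and 1 adjusted over the list alone, camera adjusted p = 0.195). They included Klrb1c, at 3.39 ± 1.32 and 10.9 ± 1.87 CPM, and Gzma, at 820 ± 500 and 2320 ± 376 CPM. Gzma also stands on the cytotoxic effector list, and 4 of the 9 NK cell markers stand on other lists. The call of Gzma was lost with robust edgeR (adjusted p = 0.0549, the highest of a range that began at 0.00073). B cell and plasma cell markers rose in 3 of 11 and fell in 0, the same adjusted over the list alone (camera adjusted p = 0.87). Their median log2 fold change was -0.18 (0.12 without control replicate 1), while the mean (0.26) and camera's direction were upward. The plasma cell marker gene Sdc1 went from 1.45 ± 0.636 to 17.7 ± 6.19 CPM and Cd22 from 0.696 ± 0.129 to 4.04 ± 2.07 CPM. Granulocyte and mast cell markers rose in 3 of 5, the same adjusted over the list alone (camera adjusted p = 0.0912, called up without control replicate 3 at 0.0209, without butyrate replicate 1 at 0.0396 and with fry at 0.00449, and 0.38 at most), with Siglecf at 0.4 ± 0.236 and 7.92 ± 1.92 CPM. Cxcr2 of this list had 1 count over the control and 73 over the butyrate libraries, a ratio of 75.1 with an exact 95% interval of 13.1 to 3010 that covers counting error only. Of 4 tested erythroid and platelet markers, too few for the list test, 2 rose (4 adjusted over the list alone). They were Epor, with 3 and 65 counts (ratio 22.3, interval 7.3 to 111), and the beta globin gene Hbb-b1, with 2 and 197 counts (ratio 101, interval 27.7 to 842). For Hbb-b1 the SD of the butyrate libraries (16.7 CPM) exceeded their mean (12.1 CPM). Its log2 fold change was 4.13 without butyrate replicate 3 and 6.44 with all libraries, and its call was lost with robust edgeR (adjusted p = 0.0526, the highest of a range that began at 1.99e-05). All 3 control counts of Epor came from control replicate 1 and the 1 of Cxcr2 from control replicate 2. Without those libraries 0 control counts are left, so no fold can be measured for these genes there.

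Among chromatin genes, histone acetyltransferase and bromodomain genes fell in 16 of 24 and rose in 0, the same adjusted over the list alone (median log2 fold change -0.43). Brpf3, a subunit of acetyltransferase complexes, went from 75.7 ± 5.82 to 24.1 ± 1.49 CPM (SD, n = 3), and Brd8 from 138 ± 2.42 to 73.8 ± 5.54 CPM. The list was called down (camera adjusted p = 6.37e-05), but not with an estimated correlation (adjusted p = 0.38). Histone deacetylase genes rose in 4 of 17 and fell in 4, the same adjusted over the list alone (camera adjusted p = 0.88). Sirt2 rose by a log2 fold change of 0.58, while Sirt1 and Hdac5 fell by 1.12 and 0.68. Hdac11 rose by 3.19, but from a level near the detection limit (0.458 ± 0.242 CPM in control and 4.45 ± 1.58 CPM with butyrate). Genes that histone deacetylase inhibitors induce in other cells rose in 11 of 21 and fell in 0, the same adjusted over the list alone. Gsn, which encodes the actin-severing protein gelsolin, went from 19.7 ± 3.17 to 114 ± 44.6 CPM, and the metallothionein gene Mt1 from 137 ± 15.2 to 268 ± 17.2 CPM. H1f0, a linker histone gene of this list, did not pass the test (221 ± 28.9 and 241 ± 23.6 CPM, edgeR adjusted p = 0.419). The list was called up (camera adjusted p = 0.0189). The call was lost with an estimated correlation (adjusted p = 0.38), without control replicate 1 (0.0504), and with the replicate block plus length and GC offsets (0.0531), and the lowest value over its alternatives was 0.00145.

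Replication-dependent histone genes rose in 26 of 37 and fell in 2 (29 and 2 adjusted over the list alone, median log2 fold change 1.21). H2bc12 went from 4.48 ± 0.731 to 13.3 ± 0.747 CPM (SD, n = 3) and H1f2 from 7.59 ± 0.339 to 16.3 ± 0.963 CPM. H2bc21 fell from 13.1 ± 2.32 to 5.21 ± 1.54 CPM, and H2aw had a log2 fold change of -1.16 (edgeR adjusted p = 0.0209). H2bc12, H1f2, H2bc21 and H2aw are among the 5 of the 37 members that also stand on the linker and replacement list. The call of H2aw was lost without control replicate 1 (log2 fold change -0.97, adjusted p = 0.0712) and without butyrate replicate 2 (-0.86, 0.0595), with a lowest value of 0.0024 over its alternatives. The list was called up (camera adjusted p = 1.25e-06), but not with an estimated correlation (adjusted p = 0.38). Most such transcripts lack a poly(A) tail, and how reads of their near-identical copies were counted is not given in the sources used here. Linker and replacement histone genes rose in 5 of 15 and fell in 6, the same adjusted over the list alone (camera adjusted p = 0.87), with H2ax, the gene of the variant phosphorylated at DNA breaks, falling from 442 ± 20.4 to 161 ± 38.5 CPM. H3f3a of this list fell by 0.75 on the log2 scale. Neuronal genes rose in 11 of 22 tested, from 64 matched, and fell in 2, the same adjusted over the list alone. Dpysl5, a gene of neurite growth, went from 0.354 ± 0.19 to 6.53 ± 2.17 CPM, while Syt11 and Tubb4a fell by 0.51 and 0.99 on the log2 scale. That list was called up (camera adjusted p = 0.0067), but not with an estimated correlation (adjusted p = 0.38).

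G2 and mitosis genes fell in 47 of 55 and rose in 0, the same adjusted over the list alone (median log2 fold change -0.84). Cdc20, an activator of the anaphase-promoting complex, went from 196 ± 15.2 to 63.4 ± 3.95 CPM (SD, n = 3), and the spindle gene Ckap2 from 110 ± 2.2 to 52.0 ± 4.15 CPM. As a list they were called down (camera adjusted p = 3.83e-14), but not with an estimated correlation (adjusted p = 0.38). S phase genes rose in 10 of 46 and fell in 10, the same adjusted over the list alone (median log2 fold change 0.01, camera adjusted p = 0.87, direction down). E2f1 and the replication helicase gene Mcm6 rose by log2 fold changes of 0.63 and 0.56, and Clspn and Brip1 fell by 0.71 and 0.53. The cell cycle inhibitor gene Cdkn1a, which encodes p21, rose from 162 ± 52.1 to 479 ± 134 CPM (log2 fold change 1.56, edgeR adjusted p = 0.00138), and Pmaip1, the gene of a pro-apoptotic protein, by 1.14. Cdkn1b, which encodes p27, fell from 148 ± 13.2 to 48.4 ± 6.95 CPM, and Cdkn2c fell by 1.58 on the log2 scale. Of 22 cyclin-dependent kinase inhibitors and p53 targets, 5 rose and 8 fell (6 and 8 adjusted over the list alone, camera adjusted p = 0.41), with a median of 0.01 and a mean of -0.0016. Apoptosis genes rose in 11 of 30 and fell in 7 (12 and 7 adjusted over the list alone, camera adjusted p = 0.624). Bcl2a1d, a survival gene of a multicopy family, rose by 2.06, and the caspase inhibitor genes Xiap and Birc3 fell by 0.98 and 0.93.

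Of the lipid pathways, cholesterol synthesis fell in 19 of 24 genes and rose in 0 (21 and 0 adjusted over the list alone, median log2 fold change -0.46). Insig1, a sterol feedback gene, went from 153 ± 16.3 to 66.9 ± 12 CPM (SD, n = 3). The list was called down (camera adjusted p = 4.27e-06), but not with an estimated correlation (adjusted p = 0.38). Fatty acid synthesis genes fell in 11 of 21 and rose in 5, the same adjusted over the list alone (median -0.37 but mean 0.08, camera adjusted p = 0.144, direction down). The desaturase genes Fads1 and Fads2 fell by 1.12 and 2.13, and the acyltransferase gene Dgat2 rose by 1.65. Mlxipl, the gene of the glucose-sensing factor ChREBP, had 3 counts over the control and 166 over the butyrate libraries, a ratio of 56.9 (exact 95% interval 19.1 to 279). Fatty acid oxidation genes rose in 10 of 44 and fell in 4 (9 and 4 adjusted over the list alone, camera adjusted p = 0.41). Pparg, a nuclear receptor gene, rose from 10.5 ± 0.513 to 43.3 ± 13.6 CPM, and Slc25a20, which carries acylcarnitines into mitochondria, by 0.55, whereas Acsl5 and Pnpla2 fell by 1.04 and 0.54. Cpt1a, the rate-limiting enzyme of mitochondrial fatty acid import, did not pass the test (133 ± 3.67 and 126 ± 2 CPM, edgeR adjusted p = 0.361). Without control replicate 3 the log2 fold change of Mlxipl was 6.46, against 5.66 with all libraries. Among genes of short-chain fatty acid transport and activation, 4 of 10 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.787). Bsg and the monocarboxylate transporter gene Slc16a1 rose by 0.57 and 0.51, and the acetyl-CoA synthetase genes Acss1 and Acss2 fell by 1.35 and 0.96.

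Glycolysis genes rose in 9 of 25 and fell in 3 (10 and 3 adjusted over the list alone, camera adjusted p = 0.13). Hk2, a hexokinase gene, went from 116 ± 13.7 to 239 ± 50.6 CPM (SD, n = 3, edgeR adjusted p = 0.000824), and Ldha, the lactate dehydrogenase gene, from 1281 ± 28.3 to 1708 ± 139 CPM (adjusted p = 0.00603). The glucose transporter gene Slc2a3 rose by a log2 fold change of 1.03, whereas Slc2a1 did not pass the test (148 ± 16.1 and 145 ± 14.6 CPM, adjusted p = 0.812). Aldoc and Pfkl fell by 1.24 and 0.32. Eno2 had 3 counts over the control and 145 over the butyrate libraries, a ratio of 49.7 (exact 95% interval 16.7 to 244), and its log2 fold change was 6.27 without control replicate 3 and 5.47 with all libraries. Tricarboxylic acid cycle and pyruvate oxidation genes rose in 6 of 36 and fell in 11, the same adjusted over the list alone (camera adjusted p = 0.183), with Pcx, the pyruvate carboxylase gene, up by 1.62, Pdp1 up by 0.62 and Idh3g and Idh1 down (log2 fold changes -0.92 and -1.33). Nuclear genes of the respiratory chain rose in 12 of 73 and fell in 3 (5 and 1 adjusted over the list alone, camera adjusted p = 0.453). Cox7a2l and Ndufv3 rose by 0.44 and 0.76, and Ndufs7 fell by 0.75. Of 11 mitochondrially encoded genes, 1 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.512). That gene, mt-Rnr1, had an adjusted p of 0.0424, which lay between 0.0577 and 0.13 in all 6 fits that left a library out and was 0.106 with no filter. Amino acid uptake and use genes rose in 10 of 32 and fell in 3, the same adjusted over the list alone (camera adjusted p = 0.41). Shmt1 and Gls2 rose by 1.12 and 1.46, and the transporter genes Slc38a2 and Slc38a1 fell by 0.44 and 0.40.

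Interferon response genes fell in 15 of 36 and rose in 10 (16 and 10 adjusted over the list alone, median log2 fold change -0.36, camera adjusted p = 0.121). Rtp4 went from 18.4 ± 3.99 to 0.841 ± 0.278 CPM (SD, n = 3) and the antiviral gene Oas3 from 165 ± 18.5 to 71.5 ± 8.52 CPM. The guanylate-binding protein genes Gbp4 and Gbp5 rose, from 383 ± 41.1 to 756 ± 64.3 CPM and from 26.2 ± 5.07 to 63.9 ± 6.94 CPM. The list was called down in 5 of 20 alternatives: without control replicate 2 (adjusted p = 0.0354), without butyrate replicate 3 (0.0492), with no filter (0.0133), with fry (0.0374) and with length and GC offsets and the block (0.0481), and the highest value was 0.714. Antigen presentation genes rose in 9 of 23 and fell in 6 (10 and 6 adjusted over the list alone, camera adjusted p = 0.363). Here the class II genes H2-Ab1 and H2-DMb1 rose by 2.10 and 2.31, while the immunoproteasome gene Psmb10 and the class I gene H2-M3 fell by 1.16 and 0.57. Heat shock and immediate early genes rose in 9 of 20 and fell in 4, the same adjusted over the list alone (camera adjusted p = 0.0912). Atf3, a stress-induced transcription factor, rose from 9.49 ± 0.773 to 52.1 ± 12.7 CPM and Ier3 by 1.46, whereas Zfp36, which encodes an mRNA-destabilizing protein, and Btg2 fell by 1.18 and 0.70. Cytosolic ribosomal protein genes rose in 43 of 76 and fell in 0 (46 and 0 adjusted over the list alone, median log2 fold change 0.31). Rpl5 went from 27.6 ± 3.32 to 64.5 ± 7.45 CPM and Rpl23 from 55.4 ± 2.19 to 90.2 ± 8.59 CPM. As a list they were called up (camera adjusted p = 1.03e-07), but not with an estimated correlation (adjusted p = 0.38).

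Rises prevailed among weakly expressed genes. In the lowest tertile of the tested genes by mean expression, 1008 of 1163 calls of at least 2-fold were higher, or 86.7% (exact Clopper-Pearson 95% interval 84.6 to 88.6). In the middle tertile, 56.9% of 288 such calls were higher (51 to 62.7), and in the highest 40.7% of 189 (33.7 to 48.1). Genes are not independent replicates, so these intervals treat as separate what may move together. In the middle tertile the direction was not settled, since 40.5% of 1681 calls were higher with no fold minimum and 50.95% without butyrate replicate 1. Nor was it in the highest tertile, since 54.8% of calls were higher with upper quartile scaling and 50% without control replicate 1.

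**Figure D3:**
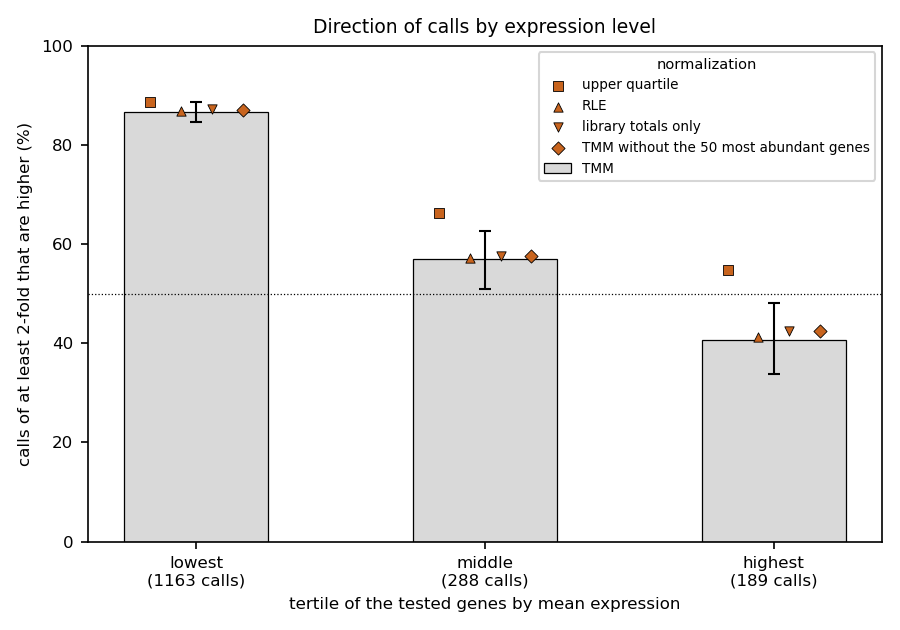
Percent of calls of at least 2-fold that were higher with butyrate (y axis), by tertile of tested genes ordered by mean expression (x axis). Bars with exact 95% intervals are from TMM scaling, and symbols from 4 other scalings. The lowest tertile stays at 86.7% or above, while the highest lies at 40.7% with TMM and 54.8% with upper quartile scaling.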

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

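The alternative with length and GC offsets was chosen after the data were seen. Counts of genes higher, lower and lower at least 2-fold stayed within 1.5 times of their values under every alternative. Of 5393 called genes, those called again in the same direction made up 79.9% to 88.5% without 1 library, 86.1% with DESeq2, 89.4% with upper quartile scaling and at least 94.5% of those tested in the other fits, and 0 were called in the opposite direction. Without 1 library, the genes higher numbered 2369 to 2633, lower 2118 to 2552, higher at least 2-fold 1238 to 1348 and lower at least 2-fold 347 to 471. The stricter filter left 810 genes higher at least 2-fold, from fewer genes tested (10526). The replicate block gave 3220 higher and 3095 lower and 5391 of the 5393 calls, changed no call of a named gene, and among lists changed only that of the cytokines, so the pairing altered no other call of a named gene or list. Scaling moved the median log2 fold change of all genes by at most 0.082. Lists called up numbered 0 with an estimated correlation and 15 with fry, and 7 to 12 without 1 library. Lists called down numbered 0 with an estimated correlation, 7 with no filter, and 4 to 5 without 1 library. Besides the lists whose changes stand in the report, fatty acid synthesis was called down with DESeq2 (adjusted p = 0.0374) and fry (0.00357), and the tricarboxylic acid cycle down with no filter (0.0465). Heat shock genes were called up with no filter (0.0447) and fry (0.00234), and fry also called up resident memory genes (0.00357), glycolysis (0.00662) and NK cell markers (0.0283). The cause of these list changes was not tested.

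In the lowest expression tertile the percent of higher calls was 88.7 with upper quartile scaling, 93.96 with no filter, 82.1 with the stricter filter, 76.0 with no fold minimum and 85.7 to 88.7 without 1 library. In the middle tertile it was 66.2 with upper quartile scaling, 79.1 with no filter, 40.5 with no fold minimum and 50.95 to 62.5 without 1 library. In the highest tertile it was 54.8 with upper quartile scaling, 48.3 with the block plus length and GC offsets, and 33.5 to 50 without 1 library. Filters change which genes make up a tertile, and the cause of the other moves was not tested. Of the 149 genes named by rule, 141 to 149 could be tested under each alternative and 0 turned direction where called. At most 6 of them lost their call under any one setting, and those values stand beside the genes described. At this depth, edgeR's test recovered 39.4% of simulated 1.5-fold changes. The simulation changed a far smaller share of genes than the 45.9% called between the groups, and the adjusted p is stricter where few genes change. The share of such changes missed in these data was therefore not measured.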

Other observations

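Tests chosen only after the result was seen were those of symbol families and RNA classes, of myeloid and B cell transcripts, of S phase genes, and of length and GC offsets. Families of genes with a shared symbol stem were tested with camera, and 6 of 129 were called, none with an estimated correlation (adjusted p = 0.91 for each of them). Small nucleolar RNA host genes (Snhg) rose in 8 of 12 and fell in 0, with a median log2 fold change of 0.55. Joining segments of the T cell receptor beta locus (Trbj) fell in 11 of 13, with a median of -1.03, and Trbc1 fell with them. Trbc2, the other constant segment, chosen after its values were seen, did not pass the test (1674 ± 106 and 1828 ± 206 CPM, edgeR adjusted p = 0.357). Genes of poly-ADP-ribose polymerases (Parp) fell in 9 of 12 and rose in 1, and centrosomal genes with the stem Cep fell in 18 of 35 and rose in 5. The stems Rpl and Rps, which take in some pseudogenes, rose in 34 of 54 and 21 of 49 members, and fell in 0 and 2.

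Macrophage and dendritic cell markers were higher with butyrate in 8 of 14 and lower in 0. The camera call of the list was lost with an estimated correlation (adjusted p = 0.38). Of the 14 markers tested, from 29 matched, 6 also stand on other lists, and 13 had at least 1 CPM in control. The 4 class II genes among them had a median log2 fold change of 1.54. The 10 tested members outside class II were split (median 0.65, SD over members 1.39). Itgam, Batf3 and Zbtb46 rose by 3.425, 3.17 and 2.43 and Tyrobp by 1.04 (adjusted p = 0.048), all called. Cd68 and Ctss stood at 0.68 and 0.62, and Lyz2, Itgax, Fcer1g and Cybb at 0.13, 0.06, -0.03 and -0.40, without passing the test. More myeloid cells in the butyrate cultures cannot be told apart from other sources. Such cells would raise these markers about as much as class II, and their median lies within the largest standard error (0.634) of 0.77, the bound set for this from the class II median. More B cells are argued against as the source of the whole rise. The 11 B cell and plasma cell markers had a median of -0.18, below 0.77 by more than their largest standard error (0.547) and below the class II median by more than the SD over them (1.49). Of these, Sdc1, Cd22 and Tnfrsf13c were called higher, 0 were called lower, and the median was 0.12 without control replicate 1, so a part from such cells stays open. Reads shared among class II genes and expression by the T cells themselves stay open and were not tested.

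Replication-dependent histone genes were higher in 26 of 37 and lower in 2 (median log2 fold change 1.21). The camera call of the list was lost with an estimated correlation (adjusted p = 0.38). A trend with transcript length or GC content is argued against as the whole cause, since with length and GC offsets and the replicate block the median was 1.15. More RNA without a poly(A) tail in the butyrate libraries cannot be told apart. The 49 other such RNAs tested, 45 of them small nucleolar, had a median of 0.42 (quartiles 0.19 and 0.60), between the bounds of 0.30 and 0.60 set for excluding it and for accepting it. Whether a larger share of cells in S phase was the cause was not settled. S phase genes did not rise as a set, with a median of 0.0078 (quartiles -0.21 and 0.22). The bounds were 0.12 for excluding this cause and 0.30 for accepting it. They were set after the result was seen, so no verdict is drawn from them. S phase genes were called both ways, 10 higher and 10 lower, so a part from such cells stays open.

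Calls in the lowest expression tertile were mostly higher (86.7%). The choice of scaling changed this little, with 86.8 to 88.7% over the 4 other scalings. Those scalings moved the median log2 fold change of all genes by at most 0.082, too little to turn many calls of at least 2-fold. They therefore cannot decide whether normalization contributed. With length and GC offsets and the block, 87.3% of these calls were higher, so the fitted trend did not account for the pattern. The offsets were fitted without the most weakly expressed genes, so a length or GC trend among those stays open. No mechanism of the treatment was tested for this pattern.

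The 6 libraries can be split 3 against 3 in 10 ways, too few to give a share under 0.05. Every split other than the real one also puts libraries of both groups on each side. The difference between the groups then counts as spread within the sides, so few gene calls were likely there, whatever the cause. As many calls as the real grouping came in 1 of the 10 splits, the real one: edgeR called 5393 genes against at most 0 in any other split, and 1640 against 0 for changes of at least 2-fold. The other splits had up to 315 genes at an unadjusted p under 0.05, and DESeq2 called at most 4 genes in them. For gene lists, 5 of the 10 splits gave 12 or more, and the highest other gave 17. Of the 4 splits that part every numbered pair, the 3 others gave at most 10 lists, and the remaining 6 keep 2 of the pairs together on one side each.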
